A study of Gossypium hirsutum with 4 samples.

How the data were processed

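Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on leaves of upland cotton, Gossypium hirsutum, an allotetraploid whose chromosomes fall into an A and a D subgenome. The 4 samples were 2 immunoprecipitates (IP), labelled D53 and B, and the input chromatin of each, with FLAG given as the antibody. Each group held 1 library. Per the labels' protocols, leaf chromatin was cross-linked with formaldehyde and sonicated, part of it was kept as input, and libraries were read as paired ends on an Illumina instrument. The labels do not say what B stands for, and they name no IP from plants without a tagged protein.

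The authors deposited 1 peak list for each IP. Per the peak names in the lists, each IP was compared with its own input, 1 library at a time and without pooling. Each list gave the sequence, start, end and name of every peak and 1 value per peak, with no header. The deposited value was handled as the authors' score: it was a whole number in each of the 18015 D53 peaks and each of the 19400 B peaks, and its definition is not given in the sources used here. Whole numbers of this kind can be a pileup height, but no source says so. The aligner, the peak caller, its threshold and the genome build are likewise not given in the sources used here. Read depth is unknown for all 4 libraries, so scores were not rescaled between lists, and no read-based interval was computed. A difference in depth or in the caller's threshold would shift scores, peak numbers and overlap.

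Because the lists held no fold enrichment, p-value or q-value, the score took the place of fold enrichment in the rule for naming peaks, which was fixed before the data were examined: the 10 peaks of highest score in each list, and the 10 overlapping pairs with the highest lower score of both. The 10 highest-scoring peaks of each list without a partner, and the pairs farthest from the median score ratio among those in which neither peak overlapped a second one, were added after the data were examined. The gene table at hand belonged to a genome assembly that could not be matched to the names used in the lists, so no peak was assigned to a gene. The planned shares per genomic feature, motif enrichment and gene list enrichment, including the strigolactone genes, were not run for the same reason. Positions are given from 1 in the coordinates of the deposited lists.

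Peaks were counted as shared when they had at least 1 bp in common. The observed overlap was set beside 1000 random placements of the D53 peaks within their own sequences, with a one-sided permutation p. Sequence lengths were not used here. The span of a sequence was taken as the highest peak end in either list, which is a lower bound of its length and is short for small scaffolds. Densities per Mb of span were compared between the 13 A and the 13 D chromosomes with a two-sided permutation test of 100000 resamples. Shares of peaks carry 95% Wilson intervals, or exact binomial intervals where stated. Intervals cover counting error of peaks only, and neighbouring peaks are not independent. Chromosome windows of 100 kb with at least 10 peaks in each list are called dense windows below. That definition was set after the data were examined. With 1 library per IP, every test here compares these lists and not the conditions.

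The overlap count was checked against bedtools 2.31.1 and gave identical numbers. The placement test was tested on simulated data on the 26 chromosomes. With 500 planted shared peaks among 9899 it returned an excess of 506, and with 2000 planted among 11407 an excess of 1999. Of 100 pairs of randomly placed lists, 4 had p at or below 0.05. These lists were placed uniformly, as in the test itself, without clusters or scaffolds. The simulation thus checks the computation and not the p for clustered peaks or for scaffolds. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Alternatives covered the overlap rule, the sequences used, score minimums, and a placement that shifts a whole list around each sequence.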

Results

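DNA bound in leaf chromatin was profiled in 2 FLAG immunoprecipitates, 1 labelled D53 and 1 labelled B. D53 is a repressor of strigolactone signalling that is degraded when the hormone is perceived, and the series concerns its action as a transcriptional repressor in cotton. FLAG is a short epitope tag. The D53 list held 18015 peaks covering 6289 kb, and the B list held 19400 peaks covering 6348 kb. There were no replicates of either IP, and read depth is unknown.

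The first question was where each IP was enriched over its own input. Peaks were narrow in both lists, with a median width of 271 bp for D53 and 252 bp for B. The median score was 8 for D53 (quartiles 5 and 15, highest 449) and 12 for B (quartiles 7 and 26, highest 663). These scores are the authors' own values. Their medians cannot be compared as binding levels, since neither their scale nor the depth is known. Only 52.3% of D53 peaks (95% Wilson interval 51.56 to 53.02) and 50.1% of B peaks (49.4 to 50.8) lay on the 26 chromosomes. Scaffolds named after a chromosome held 18.4% of D53 and 17.5% of B peaks. Unplaced scaffolds held 29.3% of D53 and 32.4% of B peaks. On chromosomes the density was 4.88 D53 peaks per Mb of span. On unplaced scaffolds it was 246 per Mb of span, a value inflated because the span of a scaffold ends at its last peak. Median scores were also higher on unplaced scaffolds than on chromosomes, at 10 against 6 for D53 and 15 against 10 for B.

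The highest-scoring peaks of each list lay mostly on scaffolds. Of the 10 highest D53 peaks, with scores of 354 to 449, 8 were on scaffolds. The exceptions were D07 51886462 to 51887466 with a score of 398 and A11 64560071 to 64561637 with a score of 362. The highest D53 peak was at 168736 to 169710 on scaffold3564_A13, with a score of 449. Of the 10 highest B peaks, with scores of 605 to 663, 8 were also on scaffolds, and the other two were A07 66323813 to 66325750 with a score of 649 and A05 62123560 to 62124248 with a score of 609. Each of these 20 peaks overlapped a peak of the other list. The D53 peaks among them had B partners with scores close to their own, for example 354 at the D07 peak and 309 at the A11 peak. The B peaks had D53 partners with far lower scores, 162 at the A07 peak and 157 at the A05 peak.

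The second question was how peaks were divided between the subgenomes. Both lists were denser on the A than on the D chromosomes. D53 peaks numbered 5.59 ± 0.42 per Mb of span on A and 3.80 ± 0.53 on D chromosomes (SD, 13 chromosomes each), a ratio of 1.47. For B the values were 5.74 ± 0.36 and 3.97 ± 0.47, a ratio of 1.44. The lowest D53 density on an A chromosome, 5.05, exceeded the highest on a D chromosome, 4.83. For B the ranges overlapped, since D05 reached 5.26 and the lowest A value was 5.08. The permutation p was 2e-05 in each list, the smallest that the resamples can give. The A chromosomes held 6465 of the 9420 D53 peaks on chromosomes, or 68.6% (exact 95% interval 67.7 to 69.6), and 68.3% of the B peaks (67.4 to 69.2), while they made up 60.0% of the span. Counts per chromosome departed from span in a chi-square test (D53 367, B 337, each with 25 degrees of freedom, p = 1.43e-62 and 2.58e-56), which treats peaks as independent. The split between subgenomes did not differ detectably between the lists, with an odds ratio of D53 over B of 1.01 (95% interval 0.95 to 1.08, Fisher's exact test p = 0.64). That test treats the lists as independent samples, although 3504 of the 9420 D53 peaks on chromosomes overlapped a B peak. Its interval and p are therefore approximate.

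**Figure D1:**
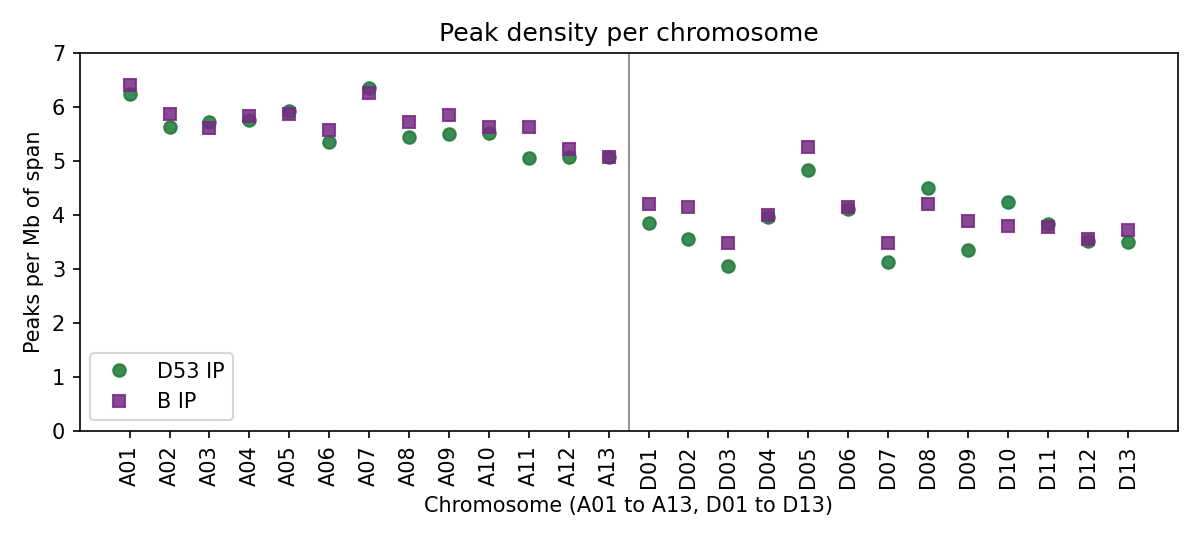
Peaks per Mb of span (vertical axis) on each of the 26 chromosomes (horizontal axis), with circles for the D53 IP and squares for the B IP, 1 library each. A chromosomes lie between 5.05 and 6.40 and D chromosomes between 3.05 and 5.26 over both lists.

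The third comparison asked how far the D53 and B profiles coincided. Of the D53 peaks, 7918 overlapped a B peak, or 44.0% (95% Wilson interval 43.2 to 44.7), and 8015 B peaks, or 41.3% (40.6 to 42.0), overlapped a D53 peak. Random placement gave a mean of 2396 (95% of placements between 2350 and 2438), so the overlap was 3.30 times that value (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The random value is high because a peak cannot move far on a small scaffold. On the 26 chromosomes alone, 3504 of 9420 D53 peaks were shared, or 37.2% (36.2 to 38.2), against a random mean of 32.5, which is 108 times as many (permutation p = 0.001).

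The share of peaks in both lists rose with score. Among D53 peaks with a score under 5, 6.57% overlapped a B peak (95% Wilson interval 5.83 to 7.40). From 20 up to 49 the share was 92.5% (91.4 to 93.5), and from 50 upwards it was 95.3% (93.9 to 96.3). Among B peaks the share was 3.85% (2.51 to 5.88) under a score of 5, 68.1% (66.6 to 69.6) from 20 to 49 and 88.6% (87.4 to 89.8) from 50 upwards. The median score of D53 peaks was 16 where they overlapped a B peak and 5 where they did not. For B peaks the medians were 26 and 9. Shared peaks were also wider, with a median of 321 against 247 bp for D53. Over all sequences the random share rose with score too, from 1.45% of D53 peaks under a score of 5 to 36.3% from 50 upwards, so the ratio of observed to random fell from 4.54 to 2.62. On the 26 chromosomes alone the random share stayed between 0.29% and 0.45%, while the observed share of D53 peaks was 6.00% (5.17 to 6.96) under a score of 5 and 95.6% (93.2 to 97.2) from 50 upwards.

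**Figure D2:**
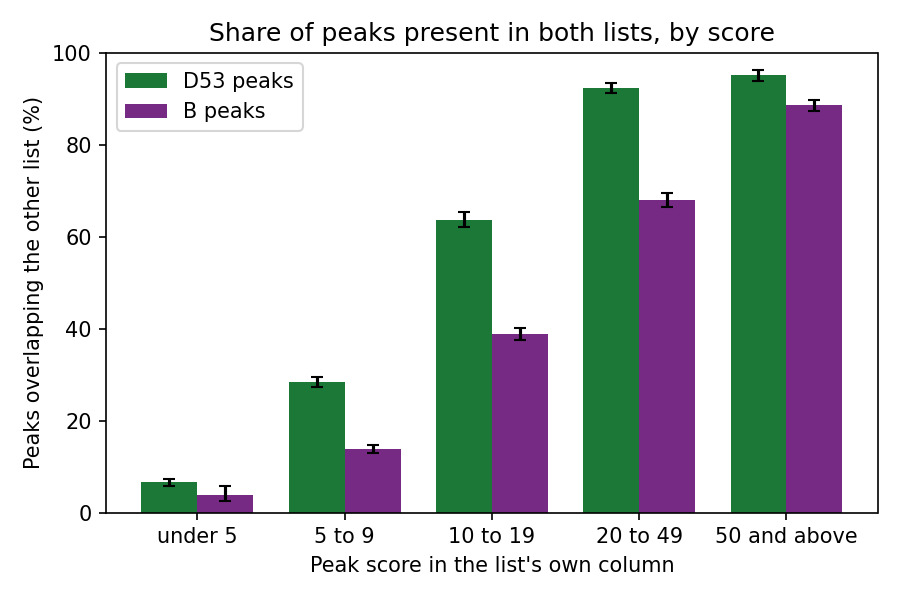
Percent of peaks that overlap the other list by at least 1 bp (vertical axis) for classes of peak score (horizontal axis), with bars for the D53 and B lists and 95% Wilson intervals as error bars. The share rises from 6.57% to 95.3% for D53 and from 3.85% to 88.6% for B.

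The 10 overlapping pairs with the highest lower score of both had D53 scores of 335 to 449. This ranking favours pairs with equal scores by construction, and pairs such as the highest B peak, with a score of 663 against 170 for D53, fall outside it. On unplaced scaffold11320 the D53 peak at 1209 to 3609 scored 441 and the B peak at 1239 to 3625 scored 439. On scaffold10319 the D53 peak at 1301 to 5160 scored 442 and its B partner 424. Unplaced scaffold7624 carried 3 of the 10 strongest pairs, with D53 scores of 380, 357 and 355 and B scores of 376, 382 and 362. The D07 peak was the only one of these 10 on a chromosome. Over all 8127 overlapping pairs the scores were ranked alike, with a Spearman rho of 0.92 across peaks, which are not independent replicates and were selected by being called in both lists. The median log2 ratio of D53 to B score was -0.68 (SD 0.67 over pairs).

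Some strong peaks had no partner in the other list, more often in B than in D53. From a score of 50 upwards, 1103 of 1158 D53 peaks and 2304 of 2599 B peaks had one. On chromosomes the highest unpartnered D53 peaks were D01 17204874 to 17205096 with a score of 150, A02 16903918 to 16904174 with 138, A04 42088659 to 42088879 with 137 and A03 30387593 to 30387847 with 128. The highest unpartnered B peaks on chromosomes were A08 1904518 to 1904709 with 199, D08 39149122 to 39149565 with 177, D12 23626833 to 23627087 with 168 and A12 83773639 to 83773846 with 160. They were chosen after their values were seen, and their widths ran from 192 to 444 bp. A missing partner means only that no peak was called there in the other list. Whether the IPs differed at these sites cannot be tested with 1 library each and no read counts.

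Where a stretch was called as 1 peak in one list and as several in the other, a ratio of scores compares a peak with a fragment, so extreme ratios were taken from the 7506 pairs in which neither peak overlapped a second one. Of these, 5 lay more than 4 times above the median ratio, none of them on a chromosome, and 26 more than 4 times below it. The pairs named here were chosen after their values were seen. The pair most in favour of D53 on a chromosome was at A03 41974250 to 41974628, where D53 scored 66 and B 34, a log2 ratio of 0.96, which is less than 4 times above the median. At A03 30382872 to 30383253 D53 scored 148 against 85 for B. The pair most in favour of B on a chromosome was at D05 46437477 to 46437702, where D53 scored 12 against 92 for B, a log2 ratio of -2.94. The next was D02 40489180 to 40489467, with a score of 4 against 28 for B, a log2 ratio of -2.81. That D53 peak was 288 bp wide, while its B partner ran from 40488429 to 40489860, so peaks of unlike width are compared. Its score of 4 is also close to the lowest in the D53 list, 3. At D06 18833883 to 18834176 D53 scored 45 against 293 for B. The D02 pair lies outside the regions dense with peaks described next, and the D05 and D06 pairs lie inside them, where the median log2 ratios were -2.09 on D05 and -2.12 on D06.

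Peaks were unevenly spaced along chromosomes in both lists. There were 13 dense windows of 100 kb, forming 8 regions on A05, A07, D05, D06, D08 and D12. They held 287 D53 peaks, or 3.05% of those on chromosomes, in 1.3 Mb. The largest regions were A05 62100001 to 62400000 with 84 D53 and 90 B peaks, A07 68600001 to 68900000 with 70 and 76, D08 15400001 to 15500000 with 45 and 51, and D05 46400001 to 46600000 with 43 and 52. The other regions were at D06 18800001 to 18900000, A07 66300001 to 66400000, D06 6800001 to 6900000 and D12 37300001 to 37400000, with 10 to 13 D53 peaks each. Of the D53 peaks in these windows 98.3% (95% Wilson interval 96.0 to 99.3) overlapped a B peak, and of the 322 B peaks 86.0% (81.8 to 89.4) overlapped a D53 peak. Their median score was 39 for D53 and 138.5 for B, against 6 and 10 on the chromosomes outside. The median log2 ratio of D53 to B score was -2.01 (SD 0.42, 284 pairs) inside and -0.58 (SD 0.51, 3349 pairs) on the chromosomes outside. In pairs without a second partner it was -2.01 (SD 0.34, 268 pairs) inside and -0.58 (SD 0.48, 2994 pairs) outside. The 8 regional medians lay between -2.19 and -1.87.

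**Figure D3:**
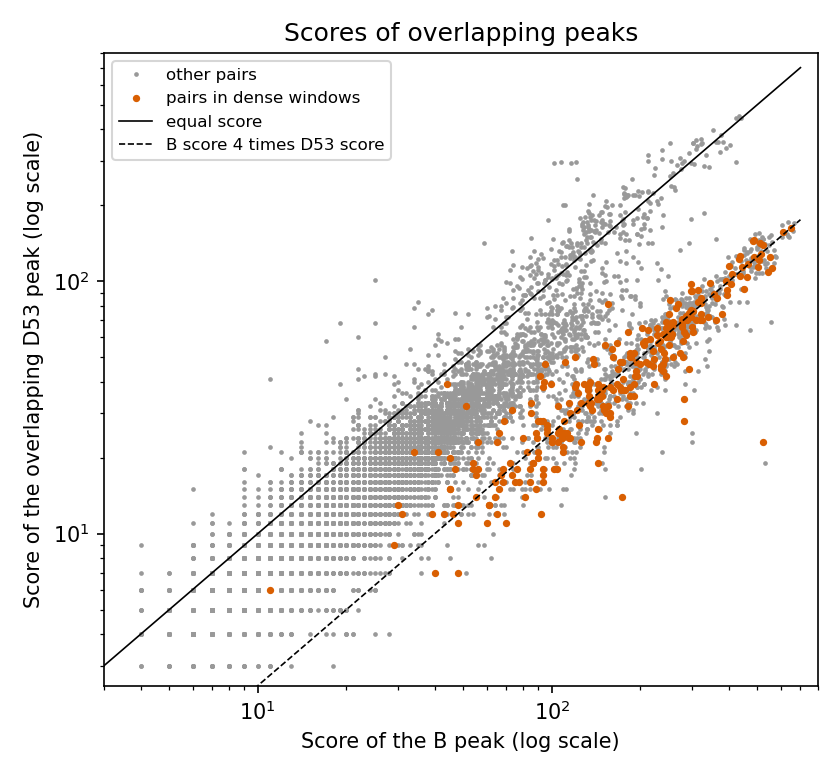
Score of each B peak (horizontal axis, log scale) against that of the overlapping D53 peak (vertical axis, log scale) for 8127 pairs, with pairs in dense windows in orange, a solid line at equal scores and a dashed line where the B score is 4 times the D53 score. Pairs in dense windows follow the dashed line, with a median log2 ratio of -2.01.

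**Figure D4:**
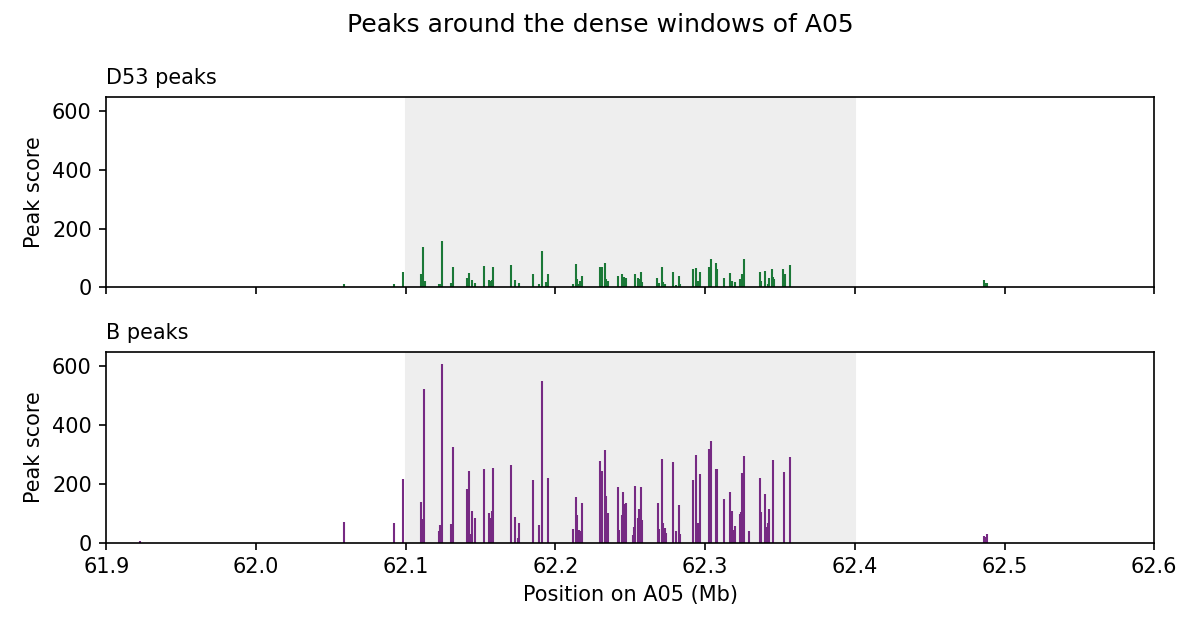
Peak score (vertical axis, unit of the authors' lists) at each peak's midpoint along part of A05 (horizontal axis, Mb), with D53 peaks in the upper and B peaks in the lower panel, and the 3 dense windows shaded grey. The shaded 300 kb holds 84 D53 peaks, the highest scoring 157, and 90 B peaks, the highest scoring 609.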

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

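The overlap of both lists exceeded random placement in every alternative run (permutation p = 0.001 each), at 2.80 times the random mean with scores of at least 20 and 108 times on the 26 chromosomes, the range over settings. The share of D53 peaks that overlapped a B peak, 44.0% as reported, moved beyond its interval in each alternative except the shifted placements, which leave it as it is. It fell to 41.8% when at least 50% of the shorter peak had to be covered, to 38.8% with midpoints at most 200 bp apart and to 35.1% with at least 50% of both peaks covered. It was 37.2% on the 26 chromosomes and 35.3% there without dense windows. It was 70.2% among peaks above the median score of each list and 92.8% with scores of at least 20. The share of B peaks that overlapped a D53 peak was lower there, at 61.8% and 54.1%. A score of at least 20 kept 3581 D53 but 6302 B peaks, so it is not a like cut in both lists. The settings without dense windows, above the median score and with scores of at least 20, and the shifted placements, were chosen after seeing the data. Fewer sequences or peaks entered by construction where a class was left out. The rules on 50% coverage could not raise the share, since they keep only part of the pairs with at least 1 bp in common. For the midpoint rule the cause was not tested. The share of chromosome peaks on A stayed above the A share of span in every alternative on chromosomes, from 68.6% to 73.4% for D53 and from 68.3% to 71.7% for B against 60.0% of span. With scaffolds named after a chromosome included, the shares were 72.7% and 72.4% against 62.8% of span. All of these alternatives were chosen after seeing the data. The median score went from 8 to 6 for D53 and from 12 to 10 for B when only the 26 chromosomes were used, with or without dense windows. The planned minimums on fold enrichment and on q, placement by feature class, and all alternatives on features, motifs and gene lists were not run, since the lists give neither fold nor q and no matching annotation was used. Leaving out a replicate could not be done with 1 library per group. No paired analysis was possible because the D53 and B libraries share no replicate number and no per-library counts were given. Unknown depth limits every statement about a peak missing from one list.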

Other observations

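Of the tests in this part, those of the overlap outside dense windows, of the overlap in the highest 10% by score, of random placement in windows, and of the A share against dense windows, as well as the definition of dense windows, the score bands and the central part of chromosomes, were chosen only after the results were seen.

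Peaks called in both lists lay nearer the middle of chromosomes than the others. The central 50% of the chromosome span held 62.1% of shared D53 peaks on chromosomes (95% Wilson interval 60.5 to 63.7) and 51.6% of unshared ones (50.3 to 52.8). Averaged over chromosomes, the share was 10.6 percentage points higher for shared D53 peaks (SD 10.6, higher on 22 of 26 chromosomes, two-sided permutation p = 0.00016, adjusted p = 0.00016 over both lists). For B the difference was 13.9 points (SD 13.2, higher on 21 of 26 chromosomes, permutation p = 8e-05, adjusted p = 0.00016). Over all sequences shared peaks also had higher scores, with medians of 16 against 5 for D53 and 26 against 9 for B. The comparison was not matched on score and kept the dense windows. It therefore cannot tell a link of position with sharing from a link of position with score.

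The strongest overlapping pairs fell into separate groups by score ratio. Of 779 pairs whose geometric mean score was at least 100, 442 had a log2 ratio of D53 to B below -1.5, with a median of -2.02, and 263 had a ratio above -0.5, with a median of 0.11. Only 74 lay between these bounds. Among the 708 such pairs without a second partner, the numbers were 401 below, 241 above and 66 between. Among 3987 pairs with a geometric mean below 20, by contrast, the median ratio was -0.58 and 129 were below -1.5. The group near -2 held 111 of the 112 strong pairs in dense windows, 20 of 161 elsewhere on chromosomes, 80 of 136 on scaffolds named after a chromosome and 231 of 370 on unplaced scaffolds.

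Uniform random spacing did not account for the fullest dense window. The fullest window held 45 D53 peaks, a number reached in 0 of 1000 random placements, whose fullest windows held at most 8. Peaks were placed uniformly along each chromosome, so the result speaks only against uniform spacing. Dense windows had been picked from the same peaks, and only the fullest was tested. A candidate explanation is 1 source of multicopy DNA that gave scores about 4 times as high in the B library as in the D53 library. It predicts a narrow ratio inside the windows, and the pooled SD of the log2 ratio there was 0.418, below all 10000 draws of pairs matched on score from the rest of the chromosomes (median 0.69, 95% of draws between 0.63 and 0.76). The tables do not identify such a source, whether organelle DNA or a repeat, and the draws mix pairs of both ratio groups, which widens them. Stronger binding in the B IP over whole windows stays open as a biological explanation, if B is a tagged protein, which the labels do not say. It was not tested, and neither was a higher background in the B IP. Either could also give a narrow ratio inside the windows, so the SD does not tell these explanations from multicopy DNA.

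The positional overlap of both lists is not explained by scaffolds and dense windows as a whole, since it was 107 times the random value on the chromosomes without them. Whether weak peaks of one library missed the caller's threshold in the other stays open. The overlap was 95.7% among the highest-scoring 10% of D53 peaks and 91.0% among those of B, but the rise of overlap with score was known before this was asked, so these values do not test it. Multicopy sequence elsewhere on the chromosomes was not tested. The labels do not say what B is, and they name no IP without a tagged protein. Whether B is another tagged protein or itself such a control is unknown. Binding at common sites and background common to FLAG IPs from leaves therefore both remain open.

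Dense windows hold too few peaks to account for the higher density on A chromosomes. They contain 287 D53 peaks on A and D chromosomes together, whereas 2028 would have to leave the A chromosomes for their share of peaks to fall to their 60.0% of span. Without dense windows the A share was slightly higher, at 69.0% against 68.6% for D53 and 68.7% against 68.3% for B. A difference in repeat content or assembly between subgenomes and a difference in binding were not tested.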
